A study of Rattus norvegicus with 4 samples.

How the data were processed

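Poly(A) RNA of 4 rat ovaries, 2 from the HFHS group and 2 from the control group, was sequenced as paired 125 bp reads on an Illumina HiSeq instrument with all 4 libraries in 1 lane, per the labels' protocols. The labels differ on tissue handling: the treatment protocol describes storage of ovaries in fixative, while the extraction protocol describes freezing in liquid nitrogen right after removal. Trimmomatic 0.35, STAR 2.5.1b, RSEM 1.2.29 and the rn6 genome build are named in the submitters' processing notes; the annotation and the strand setting are not given in the sources used here. Each library has a deposited table of 23173 rows with RSEM expected counts, TPM and FPKM per the file headers, and a deposited series table gives FPKM of 22953 gene symbols in all 4 libraries. The TPM values deposited by the authors were used only to check the names of rows.

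The names in the per-library tables do not belong to the values on their rows. As deposited, 6.02 to 6.87% of TPM fell on rows named for olfactory or vomeronasal receptors, against 0.00146 to 0.00404% of FPKM in the series table. The FPKM columns of both kinds of table hold the same values in another order, so each row was named from the series table by an exact match of its 4 FPKM values at 2 decimals. This named 17997 rows, holding 99.2% of the expected counts in each library, and 0 of them carried the deposited name. As a check, 85.0% of 12266 pairs of neighbouring named rows lay on the same chromosome in the RefSeq gene table, against 6.07% with shuffled names. Not used were 3532 rows at 0 in all libraries, 1353 rows whose values fitted more than 1 row or gene, and 291 rows of 156 symbols that the series table sums over repeats. Genes are given by the symbols of the series table, with older symbols of the preset lists looked up in the RefSeq table, so that Akr1c18 is listed as Akr1c3; no coordinates were used, since no genome was provided.

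Expected counts were rounded to whole numbers. Library totals over all rows were 25399793, 37519438, 22649556 and 25449722 for HFHS replicates 1 and 2 and control replicates 1 and 2, and 3 counts, taken as the floor, equal 0.0856 to 0.127 CPM. Floors cover counting error only. CPM use these totals with TMM factors of 1.04, 0.934, 1.04 and 0.990. The labels give each library its own rat number, so each was kept as a separate animal. Libraries of 1 diet differed by far more than sampling noise. The chi-square per gene was 163 for the HFHS pair and 70.1 for the control pair. The lowest of all pairs was 41.7, between HFHS replicate 1 and control replicate 1. The median log2 fold of all genes was 0.01 with TMM, 0.02 with RLE factors and -0.04 with totals only.

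Diets were compared with the quasi-likelihood F test of edgeR 4.0.16 (two-sided, filterByExpr, TMM, diet as the only term, R 4.3.3), with Benjamini-Hochberg adjustment over 15780 genes and a threshold of 0.05. The common biological coefficient of variation was 0.389. Standard errors of log2 folds are the fold divided by the square root of F, an approximation. Levels are given as mean ± SD of CPM over 2 animals, or per library where the replicates stood apart. For 39 gene lists of cell types and pathways, fixed with the named-gene rule, the tests and most alternatives before the data were examined, camera of limma 3.58.1 compared each list with all other genes at a preset correlation of 0.01. Camera with an estimated correlation and fry stood beside it, and adjustment ran over the 39 lists. None of the 18 lists called by camera was called with an estimated correlation or by fry.

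The rule for named genes took, among genes with a mean CPM of at least 1 and groups that do not overlap, up to 12 in each direction that passed the threshold, and since 0 did, the 6 of smallest p in each direction, given as values. It also took up to 4 passing members or the 2 of smallest p from any list, and 20 genes reported in any case, of which Hsd3b1 matched no symbol and Il6 and Tnf failed the count filter. Of the genes that the rule takes, 2 are not given here. Further genes are said to be chosen after their values were seen.

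The scripts were tested on simulated counts with the means and totals of these libraries. At the spread estimated here the test recovered 4% of 50 genes changed 2-fold, 50% at 4-fold, 80% at 8-fold and 88% at 16-fold. That is 2, 25, 40 and 44 genes recovered, beside 19 false calls among 15543 genes. At a biological coefficient of variation of 0.1 the test recovered 94% at 2-fold. Simulated genes varied independently around a spread taken as exact. In the quasi-likelihood test of the real counts Aqp3, at a log2 fold of 5.94, had an adjusted p of 0.788. The recovered shares are therefore not the chance of finding such folds in these ovaries. Camera called 40 of 40 simulated lists of 25 genes raised 2-fold and 1 of 40 unchanged lists, for genes that vary independently. Alternatives were RLE factors, totals only, 2 other count filters, each library left out, DESeq2 1.42.0, edgeR's exact and robust tests, limma-voom, limma-trend on log2 of deposited FPKM plus 1 or 0.1, other thresholds, and lists without shared genes. With 1 library left out the lone ovary of that diet is assumed to vary like the other group.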

Results

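Ovaries of female Sprague-Dawley rats, an outbred laboratory stock, were profiled by poly(A) RNA sequencing after 11 weeks on 1 of 2 diets that began at weaning on day 23. Rats on the high-fat, high-sugar (HFHS) diet ate a chow with 60% of its calories from fat (5.24 kcal/g) and could drink a 32% sucrose solution beside water. Control rats ate a chow with 17% of calories from fat (3.1 kcal/g). Of 60 rats, 32 received the HFHS diet and 28 the control diet, and the 4 libraries came from 2 different animals per diet. The p-values of single genes therefore measure the spread between single animals. Those of camera with its preset correlation compare the genes of a list with other genes and do not measure that spread. Camera with an estimated correlation and fry do use it, and called 0 of the 39 lists. The series title presents the diet as a rat model of polycystic ovary syndrome, and the comparison asks which ovarian transcripts differ between the diets. The labels do not state the stage of the oestrous cycle at which each ovary was taken. The libraries held 25399793 (HFHS replicate 1), 37519438 (HFHS replicate 2), 22649556 (control replicate 1) and 25449722 (control replicate 2) expected counts. Libraries of 1 diet were not the closest pair: 966 of 15780 genes lay over 2-fold apart between HFHS replicate 1 and control replicate 1, against 1977 between the HFHS replicates and 2035 between the controls.

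Among single genes, transcription factors of the early response to stimulation had the smallest p and were higher in HFHS ovaries, although no gene passed the test over all genes. Egr2, a zinc finger transcription factor induced by growth factors, measured 24.2 ± 0.997 CPM (SD, n = 2) in HFHS ovaries and 2.45 ± 0.292 CPM in controls, a log2 fold of 3.30 (SE 0.28). Fosb, a subunit of the AP-1 transcription factor, measured 39.2 ± 5.65 against 3.98 ± 1.14 CPM, a log2 fold of 3.30 (SE 0.32). Ier3, a stress-inducible survival gene, had a log2 fold of 1.70 (SE 0.19), and Acsl3, which activates long-chain fatty acids, one of 1.56 (SE 0.18). Aqp3, a water and glycerol channel, was read at 13.0 ± 5.52 CPM in HFHS ovaries and at 0.207 ± 0.0676 CPM in controls. On the lower side, Cd68, a lysosomal protein of macrophages, measured 36.8 ± 4.58 CPM in HFHS ovaries and 97.7 ± 18.9 CPM in controls, a log2 fold of -1.41 (SE 0.22). The phosphatase gene Dusp15 had a log2 fold of -1.50 (SE 0.24), Cd5l, a protein that macrophages secrete, -2.72 (SE 0.43), and Bhmt, an enzyme of homocysteine metabolism, -1.64 (SE 0.28).

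In edgeR's quasi-likelihood test 0 of 15780 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.788. At an unadjusted p under 0.05 the same test counted 907 genes, 434 of them higher and 473 lower in HFHS ovaries. With no difference between the diets, a share of 0.05 of the 15780 genes would be expected there. DESeq2 called 155 genes (107 higher, 48 lower) and edgeR's exact test 61 (42 higher, 19 lower), 53 genes were called by both, and limma-voom called 0. The 12 genes that the rule for single genes named, 9 of them above, were all called by both DESeq2 and the exact test. They were picked for their small p on the same counts, so this overlap is no separate support. Both HFHS libraries lay above both controls for 2867 genes (18.2%) and below both for 3546 (22.5%), where chance gives 16.7% in each direction. The other 3 named genes are uncertain, since reads of gene families can be shared and a variant can remove them from a locus. Vom2r53, named as a vomeronasal receptor, was read at 38.7 ± 9.21 CPM (SD, n = 2) in HFHS ovaries against 0.729 ± 0.469 CPM, and Ly49si3, of the killer cell lectin-like receptors, at 0.337 ± 0.0481 against 3.12 ± 0.261 CPM. Ppp1r35, a centrosomal phosphatase subunit, had 0 counts in both HFHS libraries and 4.55 ± 2.66 CPM in controls, at least 45.7-fold lower in HFHS ovaries with a floor of 3 counts per library.

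Immediate early genes, the transcription factors and feedback regulators switched on first after a stimulus, were higher in HFHS ovaries as a group. Of 24 measured members 23 had both HFHS libraries above both controls, and the median log2 fold was 1.83. HFHS replicate 2 stood further from the control mean than HFHS replicate 1, with list medians of 2.32 and 0.85 on the log2 scale. Adjusted over the list alone 13 members passed, led by Egr2 and Fosb, and over all genes tested 0 passed in the quasi-likelihood test, while DESeq2 called 12 of them and the exact test 8. The competitive test camera placed the list above other genes with an adjusted p of 1.35e-34. That call was lost, at adjusted p = 0.763 with an estimated correlation, and the list kept its call and direction without any 1 of the 4 libraries, with a median of 0.86 without HFHS replicate 2.

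**Figure D1:**
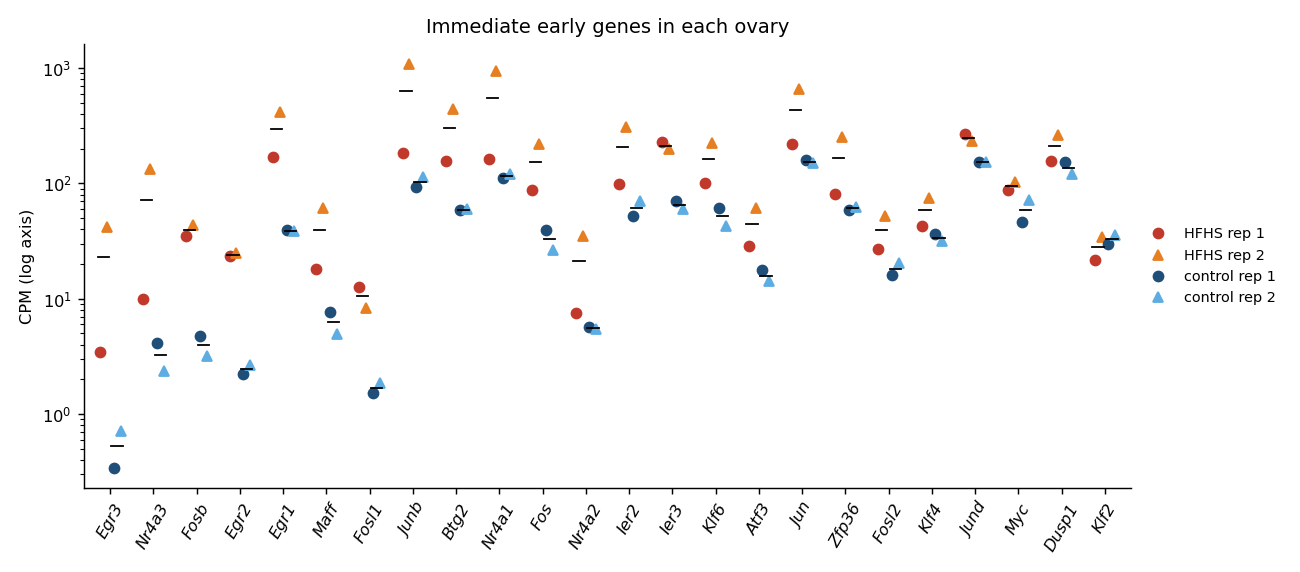
Level of each of the 24 immediate early genes in each ovary, in CPM on a log axis, ordered by fold; circles and triangles are replicates 1 and 2 of each diet and short black lines the mean of the 2 ovaries. For 23 genes both HFHS ovaries lie above both control ovaries, and Klf2, a shear-responsive transcription factor, is the exception.

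Genes of the ovulatory response to the luteinising hormone (LH) surge and genes of luteal regression were also higher in HFHS ovaries, with unequal shares of the HFHS replicates. The ovulatory list had a median log2 fold of 0.78 over 29 genes. Both HFHS libraries lay above both controls for 12 of them and below both for 3. The list median lay 1.38 above the control mean in HFHS replicate 2 and 0.52 above it in HFHS replicate 1. Adamts1, a protease of the ovulating follicle, measured 250 ± 68.3 CPM (SD, n = 2) against 61.0 ± 13.3 CPM. It and Egr1, at 294 ± 175 against 38.9 ± 0.648 CPM, were the 2 members that passed the quasi-likelihood test adjusted over the list alone; 0 passed it over all genes, while DESeq2 and the exact test each called 5. The epidermal growth factor-like ligands Areg and Ereg, chosen after their values were seen, were read at 138 and 249 CPM in HFHS replicate 2 and at 4.81 and 0.417 CPM in HFHS replicate 1, with at most 1.91 CPM in either control. Edn2, a vasoconstrictor peptide of the rupturing follicle chosen in the same way, was instead highest in HFHS replicate 1, at 32.0 CPM against 2.06 CPM in HFHS replicate 2. The camera adjusted p of the list was 1.19e-08, and adjusted p = 0.763 with an estimated correlation. Its median was 0.39 without HFHS replicate 2, 1.31 without HFHS replicate 1, and 1.63 and 1.19 without control replicates 1 and 2.

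The luteal regression list had a median log2 fold of 0.71 over 19 genes, and 4 passed the quasi-likelihood test adjusted over the list alone against 0 over all genes, while DESeq2 called 5 and the exact test 2. Ccl2, a monocyte attractant, measured 19.9 ± 3.14 CPM (SD, n = 2) in HFHS ovaries and 7.76 ± 0.422 CPM in controls. Its camera adjusted p was 7.50e-08, with adjusted p = 0.763 with an estimated correlation. Several members are also immediate early genes, and with genes of more than 1 list left out the median was 0.21 and the call ended at an adjusted p of 0.135. Inflammatory cytokine and signalling genes had a median log2 fold of 0.58 over 31 genes. Of these, 14 had both HFHS libraries above both controls and 4 had both below. The neutrophil attractant Cxcl1 measured 7.03 ± 0.0294 against 0.930 ± 0.304 CPM. This list's camera adjusted p was 6.96e-05, with adjusted p = 0.763 with an estimated correlation, and its median was 0.22 without HFHS replicate 2 and 0.28 without control replicate 2. In the quasi-likelihood test 0 members passed either adjustment, while DESeq2 called 4, Cxcl1 among them, and the exact test 1. The cytokine genes Il6 and Tnf had too few counts for the test. Il6 was read at 4.28 CPM in HFHS replicate 2 and at 0.159 to 0.341 CPM in the other ovaries, and Tnf at 0.278 to 0.455 CPM in all 4.

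Cell cycle genes were lower in HFHS ovaries. Of 36 members 31 had both HFHS libraries below both controls, and the median log2 fold was -0.78, with list medians of -0.44 in HFHS replicate 1 and -1.27 in HFHS replicate 2 against the control mean. Subunits of the helicase that opens DNA for replication led the list: Mcm6 measured 27.4 ± 2.87 CPM (SD, n = 2) against 59.1 ± 14.1 CPM, and Mcm3 19.1 ± 2.17 against 43.1 ± 10.5 CPM. In this list 0 members passed the quasi-likelihood test adjusted over the list alone or over all genes, while DESeq2 called 3 and the exact test 0. Its camera adjusted p was 1.66e-13, with adjusted p = 0.763 with an estimated correlation, and its median was -0.44 without HFHS replicate 2 and -1.29 without HFHS replicate 1.

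Macrophage and oocyte transcripts were lower in HFHS ovaries as groups. The macrophage and monocyte list had a median log2 fold of -0.46 over 20 genes, of which 12 had both HFHS libraries below both controls. Cd68 passed the quasi-likelihood test adjusted over the list alone and 0 passed over all genes, while DESeq2 and the exact test each called 1 member, Cd68. Tyrobp, a signalling adaptor of myeloid cells, measured 36.9 ± 7.49 CPM (SD, n = 2) against 66.8 ± 8.12 CPM. The camera adjusted p was 1.59e-07, with adjusted p = 0.763 with an estimated correlation, and the median was -0.18 without HFHS replicate 2 and -0.94 without HFHS replicate 1. Oocyte genes had a median log2 fold of -0.45 over 33 members, 21 of them lower in both HFHS libraries than in both controls. Tle6, of the subcortical maternal complex, measured 5.85 ± 0.357 against 10.4 ± 1.69 CPM, Zar1, a maternal-effect gene, 3.19 ± 0.171 against 5.90 ± 1.15 CPM, and Gdf9, an oocyte growth factor, 12.5 ± 0.732 against 16.3 ± 2.37 CPM. In the oocyte list 0 members passed either adjustment or were called by the other tools, the camera adjusted p was 0.000228, with adjusted p = 0.763 with an estimated correlation, and the median was -0.28 without control replicate 2.

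Oviduct epithelium genes were nearly missing from 1 control ovary and present in the other 3. Their median in control replicate 2 lay 4.18 below that in control replicate 1 on the log2 scale, and the list median log2 fold between diets was 1.13 over 16 genes. Tppp3, a tubulin-binding protein of ciliated cells, was read at 160, 142 and 96.5 CPM in HFHS replicates 1 and 2 and control replicate 1, and at 6.19 CPM in control replicate 2. Dnai2, a dynein arm subunit, measured 20.1 ± 1.64 CPM (SD, n = 2) in HFHS ovaries and 8.59 ± 10.5 CPM in controls, of which replicate 2 alone was low, at 1.19 CPM. By camera the adjusted p was 7.07e-06, with adjusted p = 0.777 with an estimated correlation, and 0.355 without control replicate 2, where the median log2 fold was 0.20; without control replicate 1 the median was 4.55. Ovarian surface epithelium genes, several of them keratins shared with the oviduct, had a median of 0.54 and a camera adjusted p of 0.0499, with adjusted p = 0.806 with an estimated correlation. The call ended with RLE factors (0.0543), with no count filter (0.0536), without genes of more than 1 list (0.0598), without HFHS replicate 1 (0.149), where the median turned to -0.43, and without control replicate 2 (0.930), where it was 0.10. Without HFHS replicate 2 and control replicate 1 the median was 0.82 and 1.28. The 6 measured uterine genes, with a median of 0.44, were not called (adjusted p of 0.163), and control replicate 2 lay 4.07 below control replicate 1 in them; they were called upwards without HFHS replicate 2 (0.00254) or control replicate 1 (0.000359). Members of these 3 lists that passed either adjustment of the quasi-likelihood test or were called by DESeq2 or the exact test numbered 0.

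Erythroid and smooth muscle lists were higher in the HFHS group. Erythroid genes had a median log2 fold of 1.53 over 12 members, with list medians of 1.78 in HFHS replicate 2 and 0.35 in HFHS replicate 1 against the control mean. The haemoglobin gene Hba1, chosen after its values were seen, was read at 6338 CPM in HFHS replicate 2 and at 949 to 1441 CPM in the other ovaries. Hemgn, a nuclear protein of red cell precursors, measured 1.69 ± 0.240 CPM (SD, n = 2) against 0.536 ± 0.141 CPM. In camera the adjusted p was 1.46e-05, with adjusted p = 0.763 with an estimated correlation; without HFHS replicate 2 it was 0.0759, with a median of 0.34, and without control replicate 1 it was 0.0565, with one of 1.45. Smooth muscle and pericyte genes had a median of 0.36 over 18 members and a camera adjusted p of 0.000228, with adjusted p = 0.763 with an estimated correlation. Without HFHS replicates 1 and 2 in turn the median was 0.55 and 0.20, and without control replicate 1 it was 0.62. Actg2, enteric smooth muscle actin, was read at 88.2 and 353 CPM in HFHS replicates 1 and 2 and at 46.6 and 25.1 CPM in the controls. The contractile regulator Cnn1 measured 105 ± 55.7 against 26.9 ± 12.0 CPM. In both lists 0 members passed either adjustment of the quasi-likelihood test, while DESeq2 called 2, Actg2 and Cnn1, and the exact test 0.

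**Figure D2:**
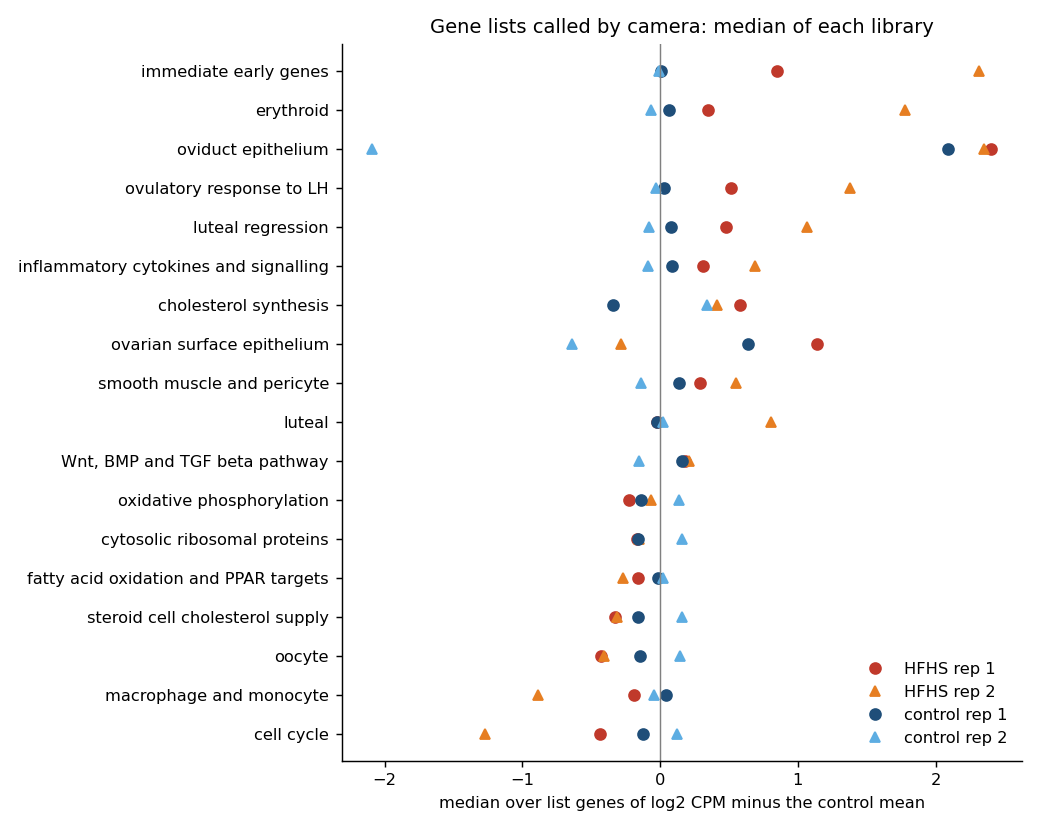
Median over the genes of each list of log2 CPM minus the control mean, 1 point per ovary, for the 18 of 39 lists that camera called with its preset correlation; circles and triangles are replicates 1 and 2. The immediate early list lies 0.85 and 2.32 above the control mean in the HFHS ovaries, and the oviduct list is low in control replicate 2 alone.

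Cholesterol synthesis genes were higher in HFHS ovaries, while genes of cholesterol uptake and storage, fatty acid oxidation and the respiratory chain were lower by small amounts. The synthesis list had a median log2 fold of 0.55 over 24 genes, 9 of them higher in both HFHS libraries than in both controls. Idi1, an isomerase of the isoprenoid pathway, measured 645 ± 315 CPM (SD, n = 2) against 182 ± 18.7 CPM, and Cyp51, a sterol demethylase, 507 ± 2.31 against 261 ± 73.3 CPM. The camera adjusted p was 8.93e-06, with adjusted p = 0.777 with an estimated correlation and 0.927 without control replicate 1, where the median was 0.22; without HFHS replicate 1 the median was 0.36 and without control replicate 2 it was 0.92. The cholesterol supply list had a median of -0.30 over 18 genes, among them Apoe, a lipoprotein ligand, at 2010 ± 236 against 3510 ± 756 CPM, and Tspo, a mitochondrial membrane protein, at 99.5 ± 5.34 against 128 ± 7.38 CPM. Its camera adjusted p was 0.00694, with adjusted p = 0.763 with an estimated correlation and 0.299 without control replicate 2, where the median was -0.18.

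Fatty acid oxidation genes had a median log2 fold of -0.20 over 32 members. Cpt2, the inner carnitine palmitoyltransferase, measured 96.6 ± 9.08 CPM (SD, n = 2) against 148 ± 0.474 CPM, and Acaa1a, a peroxisomal thiolase, 33.2 ± 0.926 against 48.3 ± 2.74 CPM. Camera gave an adjusted p of 0.00983, with adjusted p = 0.763 with an estimated correlation and 0.167 without control replicate 1. Oxidative phosphorylation genes had a median of -0.15 over 42 members and a camera adjusted p of 0.0109, with adjusted p = 0.819 with an estimated correlation. Cytosolic ribosomal protein genes also had a median of -0.15, over 52 members, with a camera adjusted p of 0.00546 and adjusted p = 0.819 with an estimated correlation. Without control replicate 2 the medians of both of these lists turned to 0.04, and without control replicate 1 they were -0.27 and -0.32. The call of the oxidative phosphorylation list also ended without HFHS replicate 1 (median -0.08, adjusted p of 0.149), and its median was -0.22 without HFHS replicate 2. Across the 5 metabolic and ribosomal lists named here 0 members passed either adjustment of the quasi-likelihood test, while DESeq2 and the exact test each called 1, Idi1.

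Luteal genes and the Wnt, BMP and TGF beta genes had small positive shifts. The luteal list had a median log2 fold of 0.34 over 17 genes, with a list median of 0.81 against the control mean in HFHS replicate 2 and of -0.02 in HFHS replicate 1. Sfrp4, a secreted Wnt inhibitor that is on both lists, was read at 102 and 297 CPM in HFHS replicates 1 and 2 and at 46.9 and 52.7 CPM in the controls. Ptgfr, the prostaglandin F receptor, measured 153 ± 22.0 CPM (SD, n = 2) against 95.3 ± 21.0 CPM. The camera adjusted p of the luteal list was 0.0325, with adjusted p = 0.806 with an estimated correlation; it was 0.723 without HFHS replicate 2, where the median turned to -0.01, and 0.667 without control replicate 1, and the median was 0.80 without HFHS replicate 1. The Wnt, BMP and TGF beta list had a median of 0.18 over 38 genes and a camera adjusted p of 0.0153, with adjusted p = 0.777 with an estimated correlation. That call ended without HFHS replicate 1 (0.0564), control replicate 1 (0.116, median 0.37) or control replicate 2 (0.208, median 0.12). Without genes of more than 1 list both calls ended, at an adjusted p of 0.233 for the luteal list and 0.156 for the Wnt, BMP and TGF beta list. Of both lists 0 members passed either adjustment of the quasi-likelihood test or were called by the exact test, while DESeq2 called Sfrp4.

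Genes that make steroid hormones were not called as a list with all 4 ovaries: of 18 measured, 3 had both HFHS libraries above both controls and 6 had both below. Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, measured 4771 ± 188 CPM (SD, n = 2) against 6517 ± 577 CPM, a log2 fold of -0.45 (SE 0.23) and an edgeR adjusted p of 0.788. Star, which moves cholesterol into mitochondria, was read at 1961 and 4925 CPM in HFHS replicates 1 and 2 and at 2706 and 2931 CPM in the controls. Cyp17a1, the theca enzyme of androgen synthesis, measured 183 ± 87.7 against 127 ± 13.7 CPM, and Cyp19a1, the aromatase, 105 ± 75.0 against 49.8 ± 33.0 CPM. The diet groups overlapped for both genes. Cyp17a1 was read at 121 and 245 CPM in HFHS replicates 1 and 2 and at 137 and 118 CPM in the controls. For Cyp19a1 these values were 51.7 and 158 CPM against 73.1 and 26.4 CPM. The gene listed as Hsd3b, chosen after its values were seen since Hsd3b1 matched no symbol, measured 9396 ± 345 against 10184 ± 1122 CPM. Hsd17b1, which makes oestradiol in granulosa cells, measured 67.6 ± 29.4 against 188 ± 94.1 CPM, and Hsd17b7, which acts in oestradiol and cholesterol synthesis, was read at 106 and 587 CPM in HFHS replicates 1 and 2 against 82.2 and 84.8 CPM. The progesterone-degrading enzyme listed as Akr1c3 was read at 3732 and 10392 CPM in HFHS replicates 1 and 2 and at 3777 and 3554 CPM in the controls. The median log2 fold of the list was 0.06, 9 genes were higher and 9 lower, 0 passed either adjustment of the quasi-likelihood test or were called by DESeq2 or the exact test, and the camera adjusted p was 0.745. The verdict turned with single libraries: the list was called downwards without HFHS replicate 2 (median -0.23, adjusted p of 0.0195) and upwards without HFHS replicate 1 (median 0.19, adjusted p of 0.00980).

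Among hormone receptors and follicle genes, Esr2 and Fshr had both HFHS libraries below both controls, while the replicates overlapped for Insr, Lhcgr, Amh and Pgr. Esr2, the granulosa oestrogen receptor, measured 4.61 ± 0.948 CPM (SD, n = 2) against 7.97 ± 2.09 CPM, and Insr, the insulin receptor, 80.9 ± 11.8 against 73.1 ± 6.76 CPM. Fshr, the FSH receptor, measured 10.7 ± 3.48 against 18.8 ± 5.80 CPM, Lhcgr, the LH receptor, 141 ± 50.1 against 163 ± 121 CPM, and Amh, a hormone of growing follicles, 156 ± 82.7 against 179 ± 54.1 CPM. Esr1, the main oestrogen receptor of stroma and epithelium, was read at 92.9 to 94.3 CPM in 3 ovaries and at 18.5 CPM in control replicate 2, the ovary low in oviduct genes. Pgr, the progesterone receptor, was read at 60.3 CPM in HFHS replicate 2, 10.1 and 11.2 CPM in the replicates 1 of HFHS and control, and 0.357 CPM in control replicate 2. Ptgs2, which makes prostaglandins at ovulation, was read at 18.2 CPM in HFHS replicate 2 and at 0.119 to 1.25 CPM in the others. Adipoq, a fat cell hormone, was read at 215 CPM in HFHS replicate 2 and at 53.0 to 67.7 CPM in the others. The edgeR adjusted p of these genes ranged from 0.788 to 0.937.

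**Figure D3:**
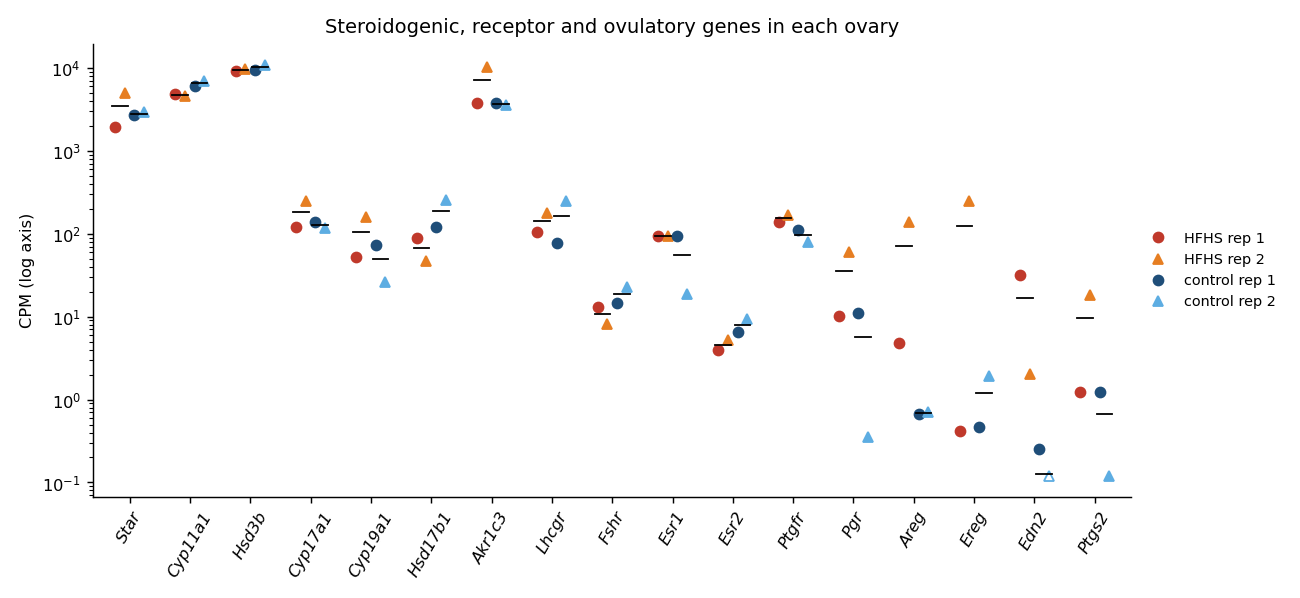
Level of 17 steroid synthesis, receptor and ovulatory genes in each ovary, in CPM on a log axis; circles and triangles are replicates 1 and 2 of each diet, short black lines the mean of the 2 ovaries, and the open triangle a count of 0 drawn at the level of 3 counts. Areg, Ereg, Pgr and Ptgs2 are highest in HFHS replicate 2 and Edn2 in HFHS replicate 1, while Cyp11a1 lies at 4638 to 4903 CPM in HFHS and 6109 to 6925 CPM in control ovaries.

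Lists of candidate genes for the disorder and of the insulin and IGF pathway were not called with all 4 ovaries, and neither were the granulosa, theca and adipocyte lists. The polycystic ovary syndrome candidate genes had a median log2 fold of 0.02 over 28 genes (camera adjusted p of 0.996), with Zbtb16, a transcription factor, at 4.45 ± 0.887 CPM (SD, n = 2) against 1.35 ± 0.00486 CPM. Insulin and IGF pathway genes had a median of 0.24 (adjusted p of 0.191), with the glucose transporter Slc2a1 at 87.6 ± 14.6 against 46.4 ± 4.95 CPM and the kinase Akt2 at 211 ± 0.387 against 404 ± 129 CPM. Granulosa genes had a median of -0.11 (0.275), with Serpine2, a protease inhibitor, at 202 ± 13.8 against 514 ± 134 CPM and the signal Ihh at 34.6 ± 5.86 against 94.4 ± 45.5 CPM. Theca and interstitial genes had a median of 0.12 (0.789), with the peptide hormone Insl3 at 12.6 and 14.3 CPM in the HFHS ovaries and 5.64 and 8.42 CPM in the controls. Adipocyte genes had a median of 0.58 (0.255), and their median excess in HFHS replicate 2 over the median of the other ovaries was 1.78 on the log2 scale. Medians and adjusted p were 0.14 and 0.501 for fatty acid synthesis, 0.25 and 0.0599 for the unfolded protein response and heat shock, 0.10 and 0.191 for hypoxia and glycolysis, and 0.01 and 0.977 for the antioxidant response. They were 0.37 and 0.111 for the circadian clock, -0.18 and 0.715 for follicle growth and oestrogen activity, and 0.03 and 0.680 for nuclear and gonadotropin receptors. Immune lists had medians of 0.04 (0.715) for the interferon response, 0.02 (0.745) for MHC class II, -0.13 (0.103) for complement, 0.21 (0.996) for lymphocytes and 0.51 (0.335) for granulocytes and mast cells. Endothelial genes had a median of 0.15 (0.297) and stromal matrix genes of 0.06 (0.745). Of the 21 lists not called with all 4 ovaries, 13 were called in at least 1 fit with a library left out. The adipocyte list was called upwards without HFHS replicate 1 (3.56e-08) or control replicate 2 (0.00155) and downwards without HFHS replicate 2 (0.000233), and its median lay 0.54 below the control mean in HFHS replicate 1. Without HFHS replicate 2, granulosa (0.0195), follicle growth (0.00616) and antioxidant genes (0.00790) were called downwards, and stromal matrix (0.00473), lymphocyte (0.0337) and MHC class II genes (0.0465) upwards. Without HFHS replicate 1, the unfolded protein response (7.35e-05), circadian clock (0.000268) and antioxidant genes (0.0353) were called upwards and complement (0.0370) downwards. Without control replicate 2, complement was called downwards (0.00130) and hypoxia and glycolysis upwards (0.0149). The median and the direction of the test differed in sign for the steroid synthesis, antioxidant and lymphocyte lists, and the median and mean for follicle growth. Among these lists 0 members passed either adjustment of the quasi-likelihood test, while DESeq2 and the exact test each called 1, Serpine2.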

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

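No gene passed an adjusted p of 0.05 with any scaling, filter, pseudocount or left-out library, by the robust test or by limma-voom; DESeq2 called 155 genes and the exact test 61, and the cause was not tested. The other thresholds, an adjusted p of 0.10 and at least 2-fold, were applied to the main fit alone and also gave 0 there. Camera called 17 or 18 lists with each scaling and count filter (RLE factors and no filter lost the surface epithelium list) and 14 without genes of more than 1 list, where the luteal (adjusted p of 0.233), luteal regression (0.135), surface epithelium (0.0598) and Wnt (0.156) lists were lost. It called 0 lists with an estimated correlation and fry called 0. Estimating the correlation also leaves camera only the degrees of freedom of the 4 animals. For the fatty acid oxidation list the estimate, -0.00858, lay below the preset 0.01, and camera's unadjusted p still went from 0.00353 to 0.0792. There the loss came with the degrees of freedom. For the other lists these 2 changes were not separated. Every other called list had an estimate above the preset, from 0.0810 (luteal regression) to 0.988 (oviduct). Among them were 0.458 (immediate early), 0.529 (cell cycle), 0.562 (erythroid), 0.602 (oxidative phosphorylation) and 0.778 (cytosolic ribosomal proteins). With 1 library left out, genes called ranged from 0 to 0 and lists from 14 to 25, and 8 of the 18 lists were called the same way each time. Of 77 single genes followed through the settings, 68 kept their sign in every setting and 9 turned only with 1 library left out. Ranges with 1 library left out, for list medians, were -0.0106 to 0.80 (luteal), -0.43 to 1.28 (surface epithelium), -0.27 to 0.0433 (oxidative phosphorylation) and -0.32 to 0.0391 (cytosolic ribosomal proteins). Those of log2 folds were -0.51 to 0.80 for Star, -0.0627 to 0.94 for Cyp17a1, -0.82 to 0.88 for Lhcgr and -0.87 to 0.26 for Amh. They were -0.31 to 1.92 for Aldh1a2, -1.50 to 8.08 for Ereg, -0.23 to 0.0275 for Hsd3b, -0.32 to 2.58 for Hbb and -1.45 to 2.88 for Hspa1a, the last 4 chosen after their values were seen. Each such fit has fewer animals. The diets gave 907 genes at an unadjusted p under 0.05; HFHS replicate 1 with control replicate 1 against the others gave 637 and HFHS replicate 1 with control replicate 2 gave 168, and 3 splits cannot give a share under 0.05. No paired analysis was possible because the labels give each animal its own number and tie no HFHS animal to a control animal.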

Other observations

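Genes of lysosomal proteins were lower in HFHS ovaries as a set. Gpnmb, a lysosomal membrane glycoprotein of lipid-laden macrophages, measured 190 ± 97.3 CPM (SD, n = 2) against 937 ± 252 CPM, Grn, the progranulin gene, 257 ± 8.65 against 424 ± 36.5 CPM, and Gm2a, a ganglioside activator protein, 754 ± 91.3 against 1692 ± 268 CPM, all 3 chosen after their values were seen. A set of 30 further lysosomal genes, fixed after those values but before its own were seen, tested whether the class is lower. Its median log2 fold was -0.24, 22 genes were lower and 8 higher, 18 of them lower in both HFHS libraries than in both controls, and camera gave p = 0.000837, with p = 0.0745 with an estimated correlation. The median ranged from -0.30 to -0.17 with 1 library left out. A lower class of lysosomal genes fits these values by the bounds set beforehand. Those bounds used camera with its preset correlation, which does not measure the spread between animals, so they do not decide a difference between the diets. The set also cannot separate fewer macrophages from less expression per cell.

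The 3 patterns below were picked after the results were seen. The tests of heat shock genes, of HFHS replicate 1 alone and of blood and fat were also written after the values they use, or values close to them, had been seen; the sets of further LH targets and cilia genes were fixed before theirs were.

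The first pattern is the higher level of immediate early genes in HFHS ovaries. It does not come from HFHS replicate 2 alone, since HFHS replicate 1 exceeded both controls for 23 of 24 genes. A longer or warmer interval before freezing could raise such genes, and the median log2 fold of 10 heat shock genes was 0.54, but only 4 of them were higher in both HFHS libraries than in both controls. Hspa1a, chosen after its values were seen, was read at 51.9 and 1063 CPM in HFHS replicates 1 and 2 and at 198 and 89.5 CPM in the controls, so handling remains open, as do an effect of diet and of cycle stage.

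The second pattern is the high level of Areg, Ereg and Pgr in HFHS replicate 2. Collection of this ovary after an LH surge fits the further LH targets, of which 8 of 14 were highest in HFHS replicate 2. Against a share of 1 in 4 the one-sided binomial p was 0.0103. That p treats genes as independent and libraries as equally likely to be highest. Over all genes HFHS replicate 2 was not the only library to stand apart. It lay over 2-fold from HFHS replicate 1 and control replicates 1 and 2 for 1977, 2148 and 3369 genes. Control replicate 2 did so from HFHS replicates 1 and 2 and control replicate 1 for 2659, 3369 and 2035 genes. The share without a surge was not measured, so the p does not decide. Of the other 6 targets, 5 were highest in HFHS replicate 1, as was Edn2. The values therefore do not show that HFHS replicate 1 had met no surge, nor tell a surge from higher levels in both HFHS ovaries. Blood or fat as a source is left open, since the 3 genes were picked for their excess: its median over the other ovaries, 7.46 on the log2 scale, was 5.33 above the larger of those of haemoglobin (2.13) and adipocyte genes (1.78), but that of Pgr was 2.57. No biological explanation by diet was tested, since cycle stage is not in the labels.

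The third pattern is the low level of oviduct genes in control replicate 2. Oviduct or other ciliated epithelium dissected with the other 3 ovaries could account for it. Of 18 further cilia genes, 17 were over 4-fold lower in control replicate 2 than in each other library. The oviduct list itself holds cilia genes such as Dnai2. The further genes therefore show that cilia genes as a class were low there, and do not test dissection as the cause. Dnah6, chosen after its values were seen, was read at 36.3 to 44.9 CPM in those 3 and at 0.159 CPM in control replicate 2. No biological explanation was tested, and the test cannot tell oviduct from ciliated cells of the ovary's own surface or cysts.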
